A study of Mus musculus with 3 samples.

How the data were processed

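RNA-seq tables of 3 mouse EpiSC libraries were used, 1 per group: NT, without inhibitor overnight; IWR1, 2 µM for 12 h; and Y27, 0.5 µM for 12 h. Groups were taken from the labels. Per the labels, total RNA was made into libraries with a standard Illumina protocol. Whether the treated cells were first kept without inhibitor is not stated.

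Per the file headers, each table gives a transcript length, an expected count and an FPKM value per gene, under Entrez Gene identifiers. The expected counts, as deposited by the authors, are estimated reads per gene with reads that match several genes shared out between them, and are not normalized. The FPKM values, as deposited by the authors, are those counts per kilobase of transcript, scaled to the summed counts. Bowtie 0.12.2 and the mm8 build are named in the submitters' processing notes, and the tool that estimated the counts is not given in the sources used here. The FPKM values were recomputed from count, length and library sum, and 91.0%, 91.3% and 90.8% of genes with over 50 counts in NT, IWR1 and Y27 came within 2%. Log2 differences and folds rest on the expected counts.

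The tables listed 15623, 15720 and 15867 genes for NT, IWR1 and Y27, with none at 0, so a gene absent from a table but present in another was taken as 0. In all 17209 genes were listed, 14353 of them in every table. Of the identifiers, 17160 (99.7%) matched a gene symbol. Names and GC content came from GRCm38 annotation, another assembly than the one the files name, so no coordinates are given. GC content was found for 99.5% of the genes compared. Whole counts made up 80.5%, 80.1% and 79.6% of the values, and the 10 highest genes held 5.40%, 4.88% and 4.38% of the counts. The genes compared had a median of 159 reads in NT.

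Counts were scaled to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.980, 0.998 and 1.02). Genes with a mean of at least 1 CPM over the 3 libraries were compared, 12955 in all, with a pseudocount of 1 CPM on the log2 scale and a 2-fold threshold. Expected counts were rounded to whole numbers for the exact conditional binomial 95% intervals of the folds, which cover counting error only. The floor for a gene at 0 was 3 counts in that library, which is 0.531, 0.536 and 0.538 CPM in NT, IWR1 and Y27. With 1 library per group no test between groups was possible. The number of genes past 2-fold was set beside 100 simulated sets of unchanged libraries with Poisson counts. The responses shared by the treated libraries were set beside the overlap of independent lists and beside unchanged libraries that share NT.

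Of 34 gene lists written before the data were examined, along with the design, the rule for naming genes and the other settings to be tried, 32 had at least 5 members above the level filter. The germ cell and the endothelial and blood lists had 4 members each and were left out. Each list's median log2 difference was set beside 10000 random lists of the same size drawn from 20 bins of mean level, and its 95% counting interval came from 500 Poisson resamplings. Lists share members: T and Cdx2, for example, stand in more than 1. Named genes were the 10 with the largest differences in each direction of each pair among genes with at least 5 CPM and 30 reads in the higher library, up to 4 members of each list and pair with the largest absolute difference, and the pathway and pluripotency genes Tnks, Tnks2, Axin1, Axin2, Ctnnb1, Rock1, Rock2, Pou5f1, Sox2, Nanog, Fgf5 and T. Unnamed gene models among the 10 were counted, not named.

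The settings tried were pseudocounts of 0.1 and 5 CPM, scaling by library total, by DESeq2 1.42.0 size factors and by upper quartile, no level filter or a mean of at least 5 CPM, thresholds of 1.5-fold and 3-fold, each row of a gene on its own, and random lists not matched on level. Chosen after seeing the data were removal of the trend of the log2 difference on length and GC content, by a cubic surface in log2 length and GC, and the use of the 10087 genes with whole counts in every library. The steps were tested on simulated data, in which genes at 5 CPM or more over the 3 libraries were set 3-fold or 4-fold apart. Of these, 100% of the higher and 98.0% of the lower passed 2-fold, and the intervals held the true fold for 94.5%. Among 12970 genes, 28 of the unchanged passed 2-fold too. Recovery of changed genes under 5 CPM was not simulated. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.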

Results

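RNA was sequenced from mouse epiblast stem cells (EpiSCs), pluripotent cells that resemble the epiblast of the embryo after implantation and that can express genes of the primitive streak, the site where mesoderm forms. The cells were grown on gelatin in serum with IWR1 and Y27632 (here Y27). IWR1 inhibits tankyrases, which stabilises Axin, a scaffold of the complex that degrades beta-catenin, and so dampens Wnt signalling. Y27632 is a kinase inhibitor that lowers actomyosin contraction. There were 3 libraries. The NT library came from cells kept overnight without either inhibitor, the IWR1 library from cells treated with 2 µM IWR1 for 12 h, and the Y27 library from cells treated with 0.5 µM Y27632 for 12 h. That dose is as labelled. It is low for this inhibitor, and its unit was not checked, so the strength of the Y27 treatment is uncertain. Each group had 1 library, so no difference given here has a replicate check and no p-value was computed. The estimated counts summed to 5767550 in NT, 5607725 in IWR1 and 5459332 in Y27. Levels are counts scaled to library size (CPM). The range after a fold is its exact 95% interval, which, like the intervals of list medians, covers counting error only. Log2 differences are log2((CPM + 1)/(CPM + 1)), which understates the differences of low genes. A gene list stands apart where its median lies outside the central 95% of 10000 random lists of the same size and level, a description of these libraries rather than a test of the treatments.

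The first comparison, IWR1 over NT, asked which transcripts differed between cells treated with IWR1 and cells kept overnight without either inhibitor. As the cells had been grown with both, a difference from NT can reflect withdrawal in NT as well as treatment. Wnt target genes were lower in the IWR1 library. Axin2 (Entrez Gene 12006), a feedback inhibitor that Wnt signalling induces, was 4.38-fold lower (3.78 to 5.09), at 39.5 CPM against 173 CPM. Sp5, a transcription factor induced by Wnt, was 5.86-fold lower (5.15 to 6.70), and Notum, a secreted enzyme that inactivates Wnt proteins, was 7.53-fold lower (2.96 to 24.5). T (Entrez Gene 20997), which encodes brachyury, the transcription factor of the streak and nascent mesoderm, was 4.63-fold lower (4.42 to 4.86), at 364 CPM against 1688 CPM. Cdx2, a caudal homeobox gene of the posterior embryo and the trophectoderm, was 19.3-fold lower (11.3 to 35.8). Of the 18 Wnt target genes used, 9 were at least 2-fold lower and 0 at least 2-fold higher. The list's median log2 difference was -0.97 (-1.14 to -0.72), below all 10000 random lists, and -0.48 over 21 genes with no filter on level. Rnf43 and Znrf3, which encode ligases that remove Wnt receptors, differed little, with log2 differences of -0.20 and -0.09. Wnt6, which encodes a Wnt ligand and was among the 10 genes with the largest negative differences, was 21.2-fold lower (11 to 47.1).

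Genes of the primitive streak and nascent mesoderm were lower as a group, with all 15 measured members below NT and 9 of them at least 2-fold. Msgn1, a transcription factor of presomitic mesoderm, was at 19.1 CPM in NT and at 0.179 CPM in IWR1, where 1 read was counted, a ratio of 107 with an interval of 18.8 to 4263. Mixl1, a homeobox gene of the streak, was at 10.8 CPM in NT and was not listed in the IWR1 library. It was at least 20.1-fold lower, against a floor of 3 counts in that library. Evx1, a homeobox gene of the posterior streak, was 10.7-fold lower (7.93 to 14.9), and Fgf17, a growth factor gene, was 4.81-fold lower (2.10 to 12.9). The list's median was -1.41 (-1.64 to -1.04), below all random lists, and -1.35 with the 2 members at 0 set to the floor. Hox genes, which pattern the body axis, showed the same direction. Hoxb1 was at 25.1 CPM in NT and 0.536 CPM in IWR1, 46.9-fold lower (15.7 to 230). The median of the 6 Hox genes used was -1.59 (-2.06 to -1.29), with 5 at least 2-fold lower. It depended on the treatment of low genes: it was -0.24 over 29 genes with no filter, and -2.74 and -0.58 with pseudocounts of 0.1 and 5, each below the random range. The streak median was -0.82 with a pseudocount of 5. Nkx1-2, a homeobox gene of the caudal epiblast, was 6.05-fold lower (4.92 to 7.51). Trophoblast markers, which share Cdx2 with the Wnt list, had a median of -0.86 over 7 genes, below the range of random lists, and of -0.27 at percentile 2.79 over 10 genes with no filter on level. Ascl2, also shared between these lists, was at 4.42 CPM in NT and 5.18 CPM in IWR1.

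Genes of the primed epiblast were higher in the IWR1 library. Fgf5, a growth factor gene that marks the post-implantation epiblast, was 3.28-fold higher (2.67 to 4.08), Otx2, a homeobox gene of the anterior epiblast, 2.01-fold higher (1.77 to 2.29), and Dnmt3b, a de novo DNA methyltransferase, 1.98-fold higher (1.88 to 2.09). The median of the 18 members was 0.47 (0.41 to 0.65), above all random lists, with 14 of 18 members higher. Core pluripotency genes had a median of 0.31 (0.25 to 0.40), at percentile 99.96, with 10 of 14 higher. Foxd3, a forkhead factor of the epiblast, was 6.66-fold higher (4.86 to 9.33), Utf1, a chromatin factor of pluripotent cells, 2.32-fold higher (2.10 to 2.57), and Sox2 1.65-fold higher (1.52 to 1.79). Pou5f1 and Nanog, the other central pluripotency factors, were at 1318 and 187 CPM in IWR1 against 1463 and 245 CPM in NT, log2 differences of -0.15 and -0.39. That of Pou5f1 turned to 0.06 once a trend with transcript length and GC content was removed. Naive pluripotency genes, which mark the pre-implantation state, had a median of -0.40 over 6 genes, at percentile 2.04, at percentile 3.70 with a pseudocount of 0.1, and at -0.20 and percentile 5.40 over 15 genes with no filter on level. Of the 6 naive genes, 4 were lower and 2 higher. Klf4 was at 2.14 CPM against 4.78 CPM, and Klf5 was 1.54-fold lower (1.28 to 1.86). Cer1, a secreted antagonist of Nodal, BMP and Wnt made in the anterior endoderm, was not listed in NT and was at 7.55 CPM in IWR1, at least 14.2-fold higher than the floor of 3 counts in NT. Trh, a hormone precursor gene also listed with definitive endoderm, was 4.16-fold higher (2.67 to 6.72). The definitive endoderm list had a median of 0.53 over 7 genes, at percentile 97.9, but of -0.08 with no filter on level and of 0.40, at percentile 94.1, with a trend of length and GC content removed. Long non-coding RNAs set as markers of RNA quality were higher too. They were Malat1, Neat1, Meg3, H19 and Xist, as none of the mitochondrially encoded genes in that list was found. Malat1 was 2.38-fold higher (2.24 to 2.53) and Neat1 2.15-fold higher (1.73 to 2.68), and the list's median was 1.07 over 5 genes, above all random lists, or 0.70 with a pseudocount of 5.

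Bone morphogenetic protein (BMP) target genes were lower in IWR1, with a median of -0.62 (-0.86 to -0.41) over 12 genes, below all random lists. Bmp4, a ligand gene, was 4.98-fold lower (3.58 to 7.28), Nog, which encodes the BMP antagonist noggin, 5.48-fold lower (3.98 to 7.71), and Msx1, a homeobox gene induced by BMP, 6.24-fold lower (3.18 to 13.6), while Smad7, an inhibitory Smad gene, was 1.59-fold higher (1.30 to 1.93). Genes of the epithelial-mesenchymal transition had a median of -0.32 over 12 genes, at percentile 0.14, and of -0.61 over the 8 with whole counts. Fn1, which encodes fibronectin, was 2.76-fold lower (2.65 to 2.87), and Snai1, a repressor of E-cadherin, 2.94-fold lower (1.95 to 4.54), while Zeb2 was 2.10-fold higher (1.86 to 2.37). YAP/TEAD target genes had a median of -0.33 over 11 genes, at percentile 0.090, and of -0.20 at percentile 3.82 with a pseudocount of 5. Amotl2 was 2.49-fold lower (2.35 to 2.64) and Ccn1 2.10-fold lower (1.97 to 2.24). Extraembryonic endoderm genes had a median of -0.42, or -0.40 with a member at 0 set to the floor, with all 10 members below NT. Lamb1, a laminin gene, was 1.66-fold lower (1.55 to 1.77). Fibroblast markers had a median of -0.33 over 10 genes, immediate early genes of -0.38 over 14 genes (-0.21 with the length and GC trend removed) and actin and SRF target genes of -0.27 over 23 genes, all below the random range. Pdgfrb, a growth factor receptor gene in the fibroblast list, was 7.02-fold lower (3.72 to 14.6), and Dusp1, a phosphatase gene in the immediate early list, 2.28-fold lower (1.96 to 2.66). Slc2a3, a glucose transporter gene, was 2.28-fold lower (2.22 to 2.36) in a hypoxia and glycolysis list whose median was -0.26, or -0.12 at percentile 5.28 once a trend with transcript length and GC content was removed. The transcripts of the inhibitor's own pathway differed by less than 2-fold. Tnks and Tnks2, the tankyrase genes, were 1.48-fold (1.31 to 1.67) and 1.26-fold (1.2 to 1.32) higher, Axin1 was at 110 CPM against 113 CPM, and Ctnnb1, which encodes beta-catenin, was 1.05-fold higher (1.01 to 1.09). The pathway list's median of 0.17 lay at percentile 97.8, and at 0.00 and percentile 67.9 once the trend was removed. The epithelial junction, Nodal/Activin, cholesterol synthesis and stress response lists lay inside the random range, with medians of -0.02, -0.09, -0.12 and 0.06. The ribosomal protein median of -0.16 lay below it, and at -0.03 and percentile 68.8 with the trend removed.

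**Figure D1:**
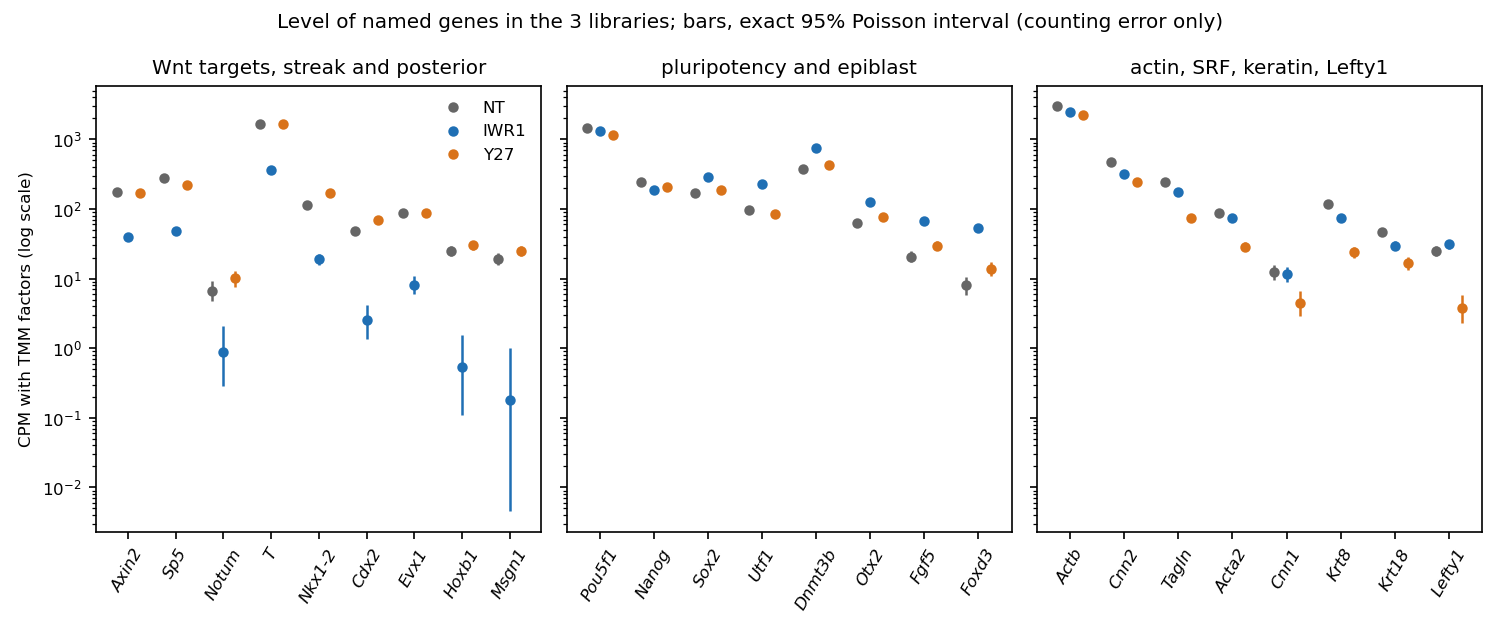
Level in CPM (vertical axis, log scale) of named genes in the NT, IWR1 and Y27 libraries, in panels for Wnt target, streak and posterior genes, for pluripotency and epiblast genes, and for actin, keratin and related genes. Points are single libraries and bars exact 95% Poisson intervals of the counts. Axin2 lies at 39.5 CPM in IWR1 against 173 CPM in NT, and Krt8 at 23.8 CPM in Y27 against 119 CPM in NT.

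Over all genes, 295 of 12955 were at least 2-fold higher in IWR1 than in NT and 292 at least 2-fold lower. Simulated unchanged libraries of the same depth gave 16.1 and 17.6 on average. Of 32 lists, 19 lay outside the central range, against 1.60 for lists of genes drawn singly at random. Members of a list can change together, and the random lists were not matched on length or GC content. The 1.60 is therefore not the number to be had without a treatment effect. Log2 differences followed transcript length and GC content, and removing this trend, a step chosen after seeing the data, left 170 genes higher and 266 lower. The share of higher genes among those past 2-fold was 50.3% before and 39.0% after. After the trend was removed, the Wnt target, streak and Hox medians were -0.89, -1.23 and -1.45, and the primed epiblast and core pluripotency medians 0.59 and 0.32. The 10 largest differences in each direction held 5 unnamed gene models among the higher genes and 1 among the lower. Several others had fractional counts, which arise when reads match more than 1 gene, and are uncertain. H2-Q8 was at 8.10 CPM in NT and H2-Q6, a related histocompatibility gene, at 0.640 CPM, whereas in IWR1 H2-Q6 was at 6.79 CPM and H2-Q8 under the floor. Fam177a and Pla2g4b, at 13.1 and 8.88 CPM in NT, were not listed in IWR1, at least 24.4-fold and 16.6-fold lower. Fsbp was 7.52-fold higher (3.18 to 18.5). Fut9, a fucosyltransferase gene with whole counts, was 9.09-fold higher (3.62 to 29.3), a log2 difference of 2.26 and of 0.99 once the trend was removed. The counts of Cer1, Foxd3 and Sp5 were partly fractional too.

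The second comparison, Y27 over NT, asked which transcripts differed under Y27632. Genes of the actin cytoskeleton, many of them targets of serum response factor (SRF), were lower in the Y27 library. Tagln (Entrez Gene 21345), which encodes the actin-binding protein transgelin, was 3.34-fold lower (2.99 to 3.74), at 73.1 CPM against 244 CPM. Acta2, smooth muscle actin, was 3.02-fold lower (2.51 to 3.62), Acta1, skeletal muscle actin, 3.53-fold lower (2.23 to 5.82), Fhl2, a LIM-domain cofactor gene, 3.60-fold lower (2.08 to 6.57), and Cnn1, which encodes calponin, 2.76-fold lower (1.73 to 4.56). Tpm1, a tropomyosin gene, was 1.64-fold lower (1.58 to 1.70), and Actb 1.33-fold lower (1.30 to 1.37). Of 23 members, 22 were lower and 6 at least 2-fold lower. The median was -0.64 (-0.74 to -0.56), below all random lists, and -0.55 once the length and GC trend was removed. Actc1, the cardiac actin gene, was 6.48-fold lower (5.02 to 8.48). Fibroblast markers, genes of another cell type, were lower alongside, with a median of -0.58 over 10 genes (-0.36 with a pseudocount of 5), and Col1a1, a collagen gene, was 2.65-fold lower (2.22 to 3.18). The counts of the actin genes Acta1, Acta2, Actb and Actc1, which have similar sequences, were partly fractional and are uncertain.

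Keratin and junction genes were lower as well. Krt8 was 5.01-fold lower (4.15 to 6.08), its partner Krt18 2.8-fold lower (2.20 to 3.59), and Krt19 3.18-fold lower (2.71 to 3.73). Cldn4, a tight junction gene, was 5.78-fold lower (2.57 to 15.3), with 7 reads in Y27. The epithelial junction list had a median of -0.54 (-0.64 to -0.31), below all random lists, with 5 of 15 members at least 2-fold lower. Lefty1 and Lefty2, secreted inhibitors of Nodal that share sequence, were 6.5-fold (4.17 to 11) and 3.24-fold (2.05 to 5.10) lower, on partly fractional counts. The Nodal/Activin list's median of -0.33, at percentile 0.360, moved to -0.16 and percentile 9.5 with the trend removed. Among matrix and surface genes with large differences, Tnc, which encodes tenascin C, was 4.85-fold lower (2.51 to 10.3), Tnfrsf12a, a cytokine receptor gene, 3.50-fold lower (2.8 to 4.41), and Cd248, with 3 reads in Y27, had a ratio of 9.87 (3.07 to 50.6). Pcdhgb5, a gene of the protocadherin cluster with fractional counts, was 6.07-fold lower (2.64 to 15.6). H2-Q6 was at 7.22 CPM in Y27 and H2-Q8 was not listed there, against 0.640 and 8.10 CPM in NT.

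Immediate early genes had a median of -0.70 (-0.81 to -0.51) over 14 genes, below all random lists. Jun was 2.15-fold lower (1.74 to 2.67), Dusp1 2.34-fold lower (2.00 to 2.73) and Ier3 2.82-fold lower (1.81 to 4.51). Stress response genes, of the integrated stress response and the unfolded protein response, had a median of -0.50 over 18 genes, 17 of them lower. Trib3, a pseudokinase gene induced by ATF4, was 2.07-fold lower (1.59 to 2.71), Herpud1, a gene of endoplasmic reticulum degradation, 2.32-fold lower (1.73 to 3.14), and Chac1, which encodes a glutathione-degrading enzyme, 2.02-fold lower (1.48 to 2.79). Cholesterol synthesis genes had a median of -0.52 over 19 genes, 18 of them lower and 0 at least 2-fold. Nsdhl, a sterol synthesis gene, was 1.87-fold lower (1.5 to 2.33), Fdft1, which encodes squalene synthase, 1.85-fold lower (1.61 to 2.14), and Idi1 1.22-fold higher (1.08 to 1.36), a log2 difference of 0.28 that turned to -0.17 with the trend removed. Hypoxia and glycolysis genes had a median of -0.47, with 17 of 18 lower, and Slc2a1, a glucose transporter gene, was 1.55-fold lower (1.49 to 1.60). The cholesterol, stress response, immediate early and glycolysis medians were -0.50, -0.35, -0.58 and -0.35 with the trend removed, all still below the random range. The list of genes with ribosomal protein symbols, which also holds kinase genes such as Rps6ka3, had a median of -0.32 over 92 genes, and of -0.13 at percentile 49.6 with the trend removed. Trophoblast markers had a median of -0.58 over 7 genes, and of -0.34 with the trend removed. Replication-dependent histone genes had one of -0.35 at percentile 2.45, and -0.15 at percentile 12.8 with the trend removed.

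The Wnt target, streak and Hox lists lay inside the random range in Y27, with medians of -0.04, -0.07 and 0.30. So did the BMP, naive pluripotency, YAP/TEAD, epithelial-mesenchymal and extraembryonic and definitive endoderm lists, with medians of -0.23, -0.32, -0.32, -0.04, 0.08 and 0.08. The YAP/TEAD median was at percentile 2.54, and at 0.390 with no filter on level. Axin2 was at 167 CPM and T at 1652 CPM, against 173 and 1688 CPM in NT. Tbx6 and Dll1, genes of presomitic mesoderm, were 2.70-fold (1.46 to 5.26) and 3.34-fold (2.15 to 5.34) higher. The primed epiblast and core pluripotency medians were 0.08 and 0.00, at percentiles 88.5 and 91.3, and 0.12 and 0.08 at percentiles 99.1 and 99.6 with the trend removed. The means of the streak and primed epiblast lists, 0.03 and -0.19, had the opposite sign to their medians, and the primed epiblast median was 0.04 with its member at 0 set to the floor. Pou5f1 was at 1163 CPM, Sox2 at 185 CPM and Nanog at 209 CPM. The drug's target genes were higher. Rock1 was 2.92-fold higher (2.46 to 3.47) and Rock2 1.84-fold higher (1.65 to 2.06), log2 differences of 1.52 and 0.87, and with the trend removed 0.62 and -0.00.

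Genes higher in Y27 outnumbered genes lower. At least 2-fold higher were 723 of 12955 genes and at least 2-fold lower 173, where unchanged libraries gave 15.9 and 18.5 on average. Zinc finger genes with related copies and fractional counts were among the 10 largest. Zfp987 was 6.78-fold higher (3.33 to 15.5), Zfp738 5.26-fold higher (3.09 to 10.1) and Zfp760 5.24-fold higher (3.62 to 7.91), and Fsbp was 9.40-fold higher (4.03 to 22.9), all uncertain through shared reads. Fut9, with whole counts, was 8.71-fold higher (3.46 to 28.2), a log2 difference of 2.21 and of 0.20 with the trend removed. Malat1 was 3.25-fold higher (3.07 to 3.45) and Meg3, an imprinted long non-coding RNA, 2.28-fold higher (2.01 to 2.60), and the RNA quality list's median was 1.18. The genes at least 2-fold higher had a median transcript length of 4328 bases and a median GC content of 41.6%, against 2891 bases and 50.5% over all genes. Across genes, which are not independent replicates, the log2 difference correlated with GC content at r = -0.51 and with log2 length at r = 0.31. With this trend removed, 206 genes were at least 2-fold higher and 150 lower, a share of higher genes of 57.9% against 80.7% before. Of the 32 lists, 12 lay outside the central range.

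**Figure D2:**
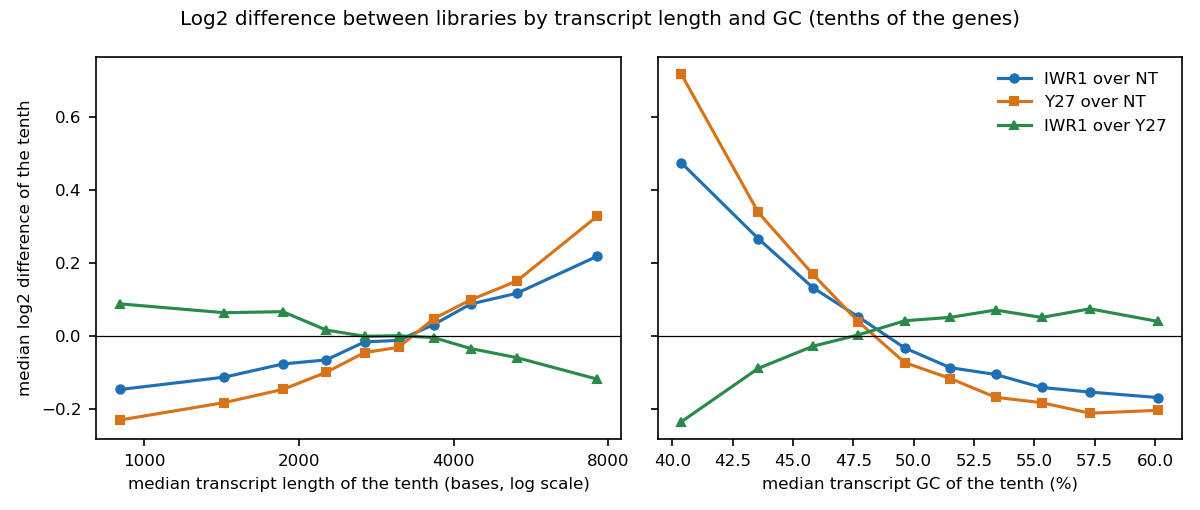
Median log2 difference (vertical axis) of genes sorted into 10 equal groups by transcript length in bases (left, log scale) and by GC content in percent (right), for the 3 pairs of libraries. The group with the lowest GC content has a median of 0.72 in Y27 over NT and 0.47 in IWR1 over NT, and the tenth with the highest has -0.20 and -0.17.

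Comparing the treated libraries with each other, IWR1 over Y27, takes the NT library out. It reuses the same IWR1 and Y27 libraries, so it is no independent check of the comparisons with NT. As the cells had been grown with both inhibitors, a difference can reflect either treatment or withdrawal of the other inhibitor. Streak and posterior genes were lower in IWR1 than in Y27, and Lefty1 and Tnc, lower in Y27 than in NT, were higher in IWR1. Evx1 was 10.7-fold lower in IWR1 than in Y27 (7.92 to 14.8), Cdx2 27.5-fold lower (16.2 to 50.8), T 4.53-fold lower (4.32 to 4.76) and Nkx1-2 8.83-fold lower (7.22 to 10.9). Hoxb1 had a ratio of 56.5 (19 to 277) on 3 reads in IWR1, and Mixl1 was at least 15.7-fold lower. Spp1, which encodes the secreted protein osteopontin, was 13.0-fold higher in IWR1 (8.74 to 20.2), Tnc 8.88-fold higher (4.75 to 18.4), Lefty1 8.15-fold higher (5.27 to 13.8), Trh 6.04-fold higher (3.59 to 10.8) and Chac1 4.38-fold higher (3.31 to 5.88). Cer1, on 3 reads and a fraction in Y27, had a ratio of 13.5 (4.46 to 70.4). Scn9a, a sodium channel gene, was 14.8-fold lower (7.41 to 29.9), Kcnj12, a potassium channel gene, 12.7-fold higher (4.35 to 68.8), and Itgb3, an integrin gene, 7.85-fold higher (2.81 to 23.4), all on partly fractional counts. Medians were -1.06 for Wnt targets, -1.34 for the streak and -1.78 for Hox genes, each below all random lists, though with no filter on level the Hox list held 29 genes and its median was -0.24, at percentile 6.84. The streak median was -1.25 with members at 0 set to the floor. They were 0.66 for primed epiblast, 0.56 for junction, 0.34 for actin and SRF, 0.37 for cholesterol and 0.37 for stress response genes, all above all random lists. Pou3f1, a POU factor of the primed epiblast, was 2.75-fold higher in IWR1 (2.40 to 3.15) and Krt8 3.16-fold higher (2.60 to 3.87). BMP target genes had a median of -0.44 and genes of the epithelial-mesenchymal transition one of -0.43. The definitive endoderm and extraembryonic endoderm lists were also outside the random range, with medians of 0.56 and -0.59. The former was 0.20 at percentile 93.9 with no filter on level, and the latter -0.27 with a pseudocount of 5. Of the lists outside it against NT in a single treated library, 6 lay inside it here. These were core pluripotency, YAP/TEAD, naive pluripotency and pathway genes, with medians of 0.17, -0.12, -0.14 and -0.04, and Nodal/Activin and histone genes, with 0.16 and 0.13. The immediate early, fibroblast, trophoblast and RNA quality lists, outside the range against NT in both treated libraries, also lay inside it here. Their medians were 0.17, 0.17, 0.16 and -0.13. For these lists a property of the single NT library cannot be told apart from a response shared by both treated libraries. At least 2-fold higher in IWR1 than in Y27 were 179 genes, and 376 were lower. The length and GC trend was weaker in this pair, and its removal left 168 and 361 genes. Of 32 lists, 14 lay outside the central range.

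Some genes differed from NT in the same direction in both treated libraries. Higher in both by at least 2-fold were 165 genes and lower in both 37, against 16.5 and 3.90 for independent lists and 3.31 and 1.25 in unchanged libraries that share NT. Fut9 and Malat1 were among the genes higher in both, and Krt19, at 118 CPM in NT, 55.0 CPM in IWR1 and 37.1 CPM in Y27, among those lower in both with Dusp1. With the trend removed, none of these 4 was past 2-fold in both libraries: Malat1 was at 0.78 and 0.99, Fut9 at 0.99 and 0.20, Krt19 at -0.88 and -1.38 and Dusp1 in Y27 at -0.99 on the log2 scale. Vim, which encodes vimentin, was 1.77-fold (1.71 to 1.84) and 1.92-fold (1.86 to 1.99) lower. In opposite directions, 1 gene was higher in IWR1 and lower in Y27, Spp1, and 7 were lower in IWR1 and higher in Y27. Independent lists would give 3.94 and 16.3. Across genes the log2 differences correlated at r = 0.58, against 0.50 in unchanged libraries sharing NT, with a covariance of 0.14 against 0.02. With the trend removed, 50 genes were higher in both and 27 lower in both, r was 0.44 and the covariance 0.08. Unchanged libraries were not simulated for that step, so these values have no such reference. Both comparisons used the single NT library, which cannot be split, so its own error enters both.

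**Figure D3:**
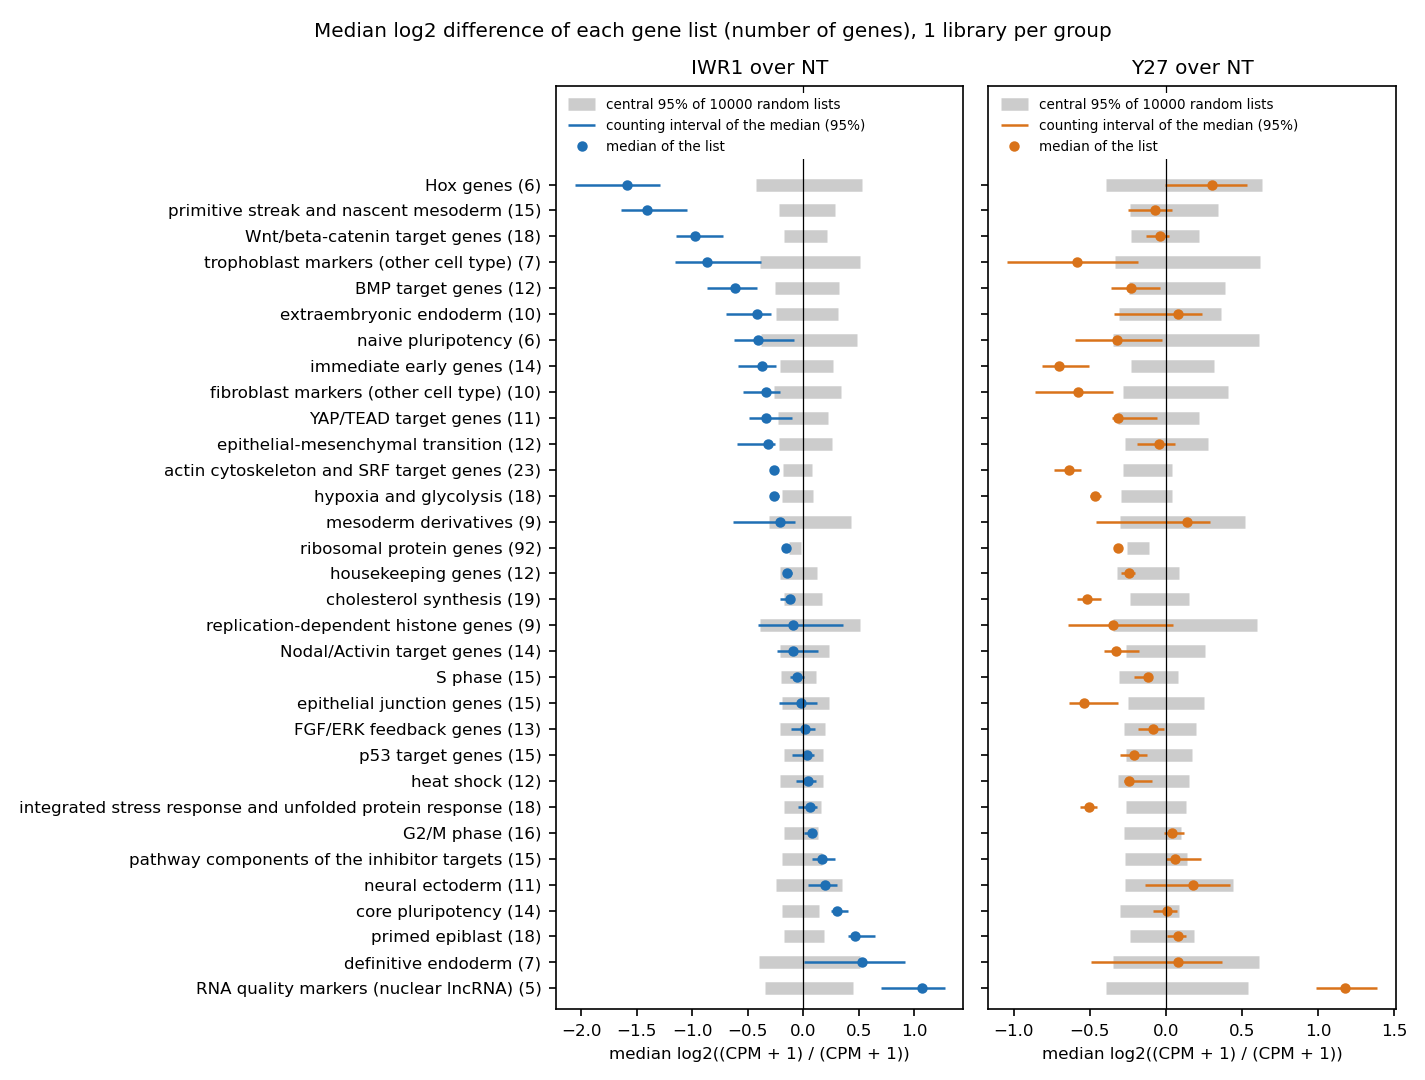
Median log2 difference (horizontal axis) of each of the 32 gene lists, with its number of genes, for IWR1 over NT (left) and Y27 over NT (right). Points are medians, lines 95% counting intervals and grey bars the central 95% of 10000 random lists matched on level. The Wnt target list lies at -0.97 on the left and -0.04 on the right, and the actin and SRF list at -0.27 and -0.64.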

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

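Removing the length and GC trend and using whole counts only were chosen after the results were seen; the other settings were chosen before. Scaling by library total, by median ratio or by upper quartile, or using no filter on mean level, left all 8 counts of genes (higher and lower in each of the 3 pairs, and shared) within 1.5 times their value. Over all alternatives 45 counts stayed within that margin and 43 moved. All 8 moved at thresholds of 1.5-fold and 3-fold, which change the count by definition, and at a pseudocount of 5. At a pseudocount of 0.1, 7 moved, and at a mean of at least 5 CPM 6 did. Pseudocount and filter act mostly on low genes. For IWR1 over NT (295 higher, 292 lower), Y27 over NT (723, 173), IWR1 over Y27 (179, 376) and shared genes (165 higher in both, 37 lower in both), a pseudocount of 0.1 gave 543 and 463 for IWR1 over NT, 320 lower for Y27 over NT, 311 and 595 for IWR1 over Y27, and 338 and 74 shared. A pseudocount of 5 gave 80 and 98, 340 and 42, 53 and 146, and 43 and 5. A mean of at least 5 CPM gave 185 and 183 for IWR1 over NT, 96 lower for Y27 over NT, 91 and 224 for IWR1 over Y27 and 16 lower in both. A threshold of 1.5-fold gave 1404 and 825, 1928 and 717, 656 and 1062, and 974 and 198, and a threshold of 3-fold 43 and 79, 80 and 27, 35 and 107, and 13 and 1. The share of higher genes in IWR1 over NT was 63.0% at 1.5-fold and 35.2% at 3-fold, against 50.3%. With the length and GC trend removed, 170 genes were higher in IWR1 over NT, 206 in Y27 over NT and 50 in both. With whole counts in every library only, which leaves fewer genes, these were 181, 429 and 93. Of the list medians, 876 stayed inside their counting interval, 56 moved and 1 reversed: definitive endoderm in IWR1 over NT was -0.0788 with no filter on mean level, which adds 3 low genes to its 7, and the cause was not tested. Of the named genes' log2 differences, 4631 stayed inside their interval, 342 moved, 191 of them with the trend removed, and 1 of those past 2-fold reversed: Xist in Y27 over NT was -0.15 with the trend removed, from 1.10, as that step takes out what its length and GC content predict. Some of these results were fixed in advance. Random lists not matched on level cannot change a list's median, and gave 96 of those that stayed. Using whole counts only left each named gene's value unchanged, with 700 inside their interval and 11 outside. Those 11 were outside because the pseudocount shifts the log2 difference from the fold. Differences under 2-fold were not counted as reversed, and some changed sign there, such as Idi1 in Y27 over NT, from 0.28 to -0.17. Of the 19 lists outside the random range in IWR1 over NT, 15 were outside with the trend removed and 15 with no filter; of the 12 in Y27 over NT, 9 and 12 were. The Wnt target, streak and Hox lists in IWR1 over NT, and the actin, junction, cholesterol and stress response lists in Y27 over NT, were outside under each alternative in which they had enough members. Taking each row of a gene on its own gave no separate value, as each gene has 1 row. Depth limits the low genes: 3 reads correspond to 0.531 CPM in NT, and a gene at 5 CPM has under 30 reads, so that its folds carry wide intervals.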

Other observations

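The cell cycle, p53, neural, mesoderm derivative, FGF/ERK feedback and heat shock lists lay inside the random range for both inhibitors over NT. Each still held single genes past 2-fold. In the G2/M list, with medians of 0.08 in IWR1 and 0.04 in Y27, the proliferation marker Mki67 was at 158, 303 and 419 CPM in NT, IWR1 and Y27, the centromere genes Cenpe and Cenpf at 74.7, 117 and 198 CPM and at 108, 194 and 311 CPM, and the checkpoint kinase Bub1 at 74.8, 121 and 179 CPM. With the length and GC trend removed their log2 differences in Y27 were 0.92, 0.69, 0.70 and 0.58. The S phase medians were -0.06 and -0.12. In the p53 target list, with medians of 0.03 and -0.21, the cell cycle inhibitor Cdkn1a was 1.63-fold lower in IWR1 (1.48 to 1.79), and the apoptosis gene Pmaip1 2.06-fold (1.74 to 2.44) and 2.11-fold (1.79 to 2.51) higher in IWR1 and Y27, at 0.74 and 0.66 on the log2 scale with the trend removed. In the neural list, with medians of 0.20 and 0.18, Gbx2, a homeobox gene of the hindbrain boundary and the posterior epiblast, was 7.18-fold lower in IWR1 (2.52 to 28.1), and Tubb3, a neuronal tubulin gene with fractional counts, was 2.25-fold lower in Y27 (1.77 to 2.88).

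In the mesoderm derivative list, with medians of -0.21 and 0.14, 2 of 9 genes were at least 2-fold lower in IWR1 and 1 higher. With the length and GC trend removed, its members Bmp4 and Pdgfra were at -2.05 and -1.32 in IWR1. Isl1, a LIM-homeobox gene, was at 19.6, 12.7 and 30.8 CPM in NT, IWR1 and Y27, under 2-fold from NT in both. In the list of FGF/ERK feedback genes, with medians of 0.01 and -0.08, the phosphatase gene Dusp4 was 2.22-fold lower in IWR1 (1.95 to 2.52) and Phlda1 3.17-fold lower in Y27 (2.40 to 4.22). In the heat shock list, with medians of 0.05 and -0.25, Hspb1, a small chaperone gene, was 2.46-fold lower in Y27 (2.18 to 2.79). The housekeeping medians were -0.15 and -0.24. Zinc finger genes with Zfp symbols, a family chosen after its values were seen, had medians of 0.27 and 0.42 over 351 genes. In Y27, 97 of them were at least 2-fold higher and 1 lower, and 9 and 2 with the trend removed. Their median GC content was 44.6%.

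The tests of a wrong label, of fewer streak-like cells and of fewer fibroblasts were chosen after the result was seen, and removal of the length and GC trend was added after the data were seen. More genes were at least 2-fold higher than lower in Y27 over NT, 723 against 173. Counting error at this depth is excluded, since simulated unchanged libraries gave 15.85 higher genes on average. A transcript length and GC trend between libraries is a candidate explanation: with the trend removed the ratio of higher to lower genes was 1.37. Whether a larger share of nuclear RNA contributed cannot be told. The median of 392 long non-coding RNA genes after trend removal was 0.238 (0.160 to 0.309 from a bootstrap over genes). Malat1, Neat1, Meg3, Snhg14, Ftx and Xist were left out, since their values had been seen. The median and its interval lay above the bound set for no larger share, but the interval crossed the bound set for one. No biological explanation was tested, the treatment included, and with 1 library each a difference in RNA or library preparation stays open.

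Wnt target genes were lower in IWR1 over NT, as the inhibitor's known action on Axin would give. Removing the length and GC trend left the median at -0.89, below all random lists, which excludes the trend as the whole cause. A single wrong or exchanged label cannot be told apart: Axin2, Sp5, Notum and Nkd1 (named after its values were seen), 4 of 4, were lowest in the library labelled IWR1, but they were picked from this pattern, and with 1 library per group no other library checks a label. Fewer streak-like cells in the culture would lower the streak list as a whole, and 0 of its members at 5 CPM or more in NT had a counting interval that included no difference, but the members did not share 1 factor (T 4.63-fold, 4.42 to 4.86; Evx1 10.7-fold, 7.93 to 14.9), which argues against the loss of 1 uniform kind of cell. The loss of a mixture of cells, or of cells whose genes other cells also express, cannot be told apart from lower transcription in each cell, because bulk RNA does not separate cell number from level, so a direct response to tankyrase inhibition stays a hypothesis.

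Actin and SRF target genes were lower in Y27 over NT. Removing the length and GC trend left the median at -0.55, below all random lists, so the trend is excluded as the whole cause. Fewer fibroblasts in the culture cannot be told apart from lower transcription in the EpiSCs, because the 4 listed of 5 abundant fibroblast transcripts summed to 17.3 CPM in NT and were 6.05 CPM lower in Y27, where Tagln alone was 171 CPM lower. This smaller loss does not decide, because the sum left out other fibroblast markers that were lower in Y27, such as Col1a1. Of the 10 fibroblast list members used, 9 were lower in Y27, but 9 were lower in IWR1 too. Between IWR1 and Y27 the list lay inside the random range, with a median of 0.17 at percentile 93.2. Also, 17.3 CPM was slightly over 0.1 of the Tagln difference, the bound set for excluding fibroblasts. A response of the cells to Y27632 itself stays a hypothesis, from 1 library per group. For both inhibitors, a response of the NT cells to withdrawal cannot be told apart from a response to treatment.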
